A study of Mus musculus with 32 samples.

How the data were processed

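RNA from 32 neurosphere cultures of mouse brain tumours was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. Per the labels' protocols, tumour cells that expressed the transgenes were sorted by flow cytometry and grown as neurospheres, and total RNA was extracted with the Qiagen AllPrep kit. The deposited values are log2 expression values, 1 per probe set and array, made by the authors with the robust multi-array average (RMA) in Affymetrix Expression Console 1.0, per the submitters' processing notes. RMA corrects the background, applies quantile normalization across arrays and summarises the probes of a set. That the scale is log2 was read from the values, which ran from 1.44 to 14.5 with array medians between 5.59 and 5.79. Filters and pooling of samples are not given in the sources used here. Because RMA gives every array the same distribution of probe values, an overall rise or fall of RNA in 1 group would not be seen, and weak probe sets are drawn towards a common floor, which understates their changes. No detection values or scan batches were used here, so the precision of a value was judged from the spread between arrays alone.

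Of 35557 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12147 were not listed there. Only probe sets with 1 symbol were used, and 99.58% of them were found in the RefSeq gene table of assembly GRCm38.p6, which served only for chromosome membership and gene order. Where a gene had several probe sets (999 genes), the one with the highest mean over all arrays was taken, which left 19938 genes. Genes without a probe set of their own in the annotation, Hras among them, were not analysed here. Every array was assigned to 1 of 8 groups from its label, and all columns of the value table matched a sample.

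Gene tests used limma 3.58.1 in R 4.3.3. One linear model with a mean for each of the 8 groups was fitted to all 32 arrays, 12 pairwise contrasts and the difference between the Bmi1 effects in MYC and HRAS cells were taken, and variances were moderated with eBayes. All adjusted p-values of genes come from this 2-sided limma test with Benjamini-Hochberg adjustment over the 19938 genes of 1 comparison, and a gene passed at adjusted p under 0.05. Fitting all groups together lets groups of 2 arrays borrow the spread of the others, so their p-values assume a common spread. Changes are given as log2 differences with the standard error of the fit.

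Gene lists were tested with camera of the limma package, 2-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. An alternative estimated the correlation of each list from the residuals, and 17 of the 73 calls among 312 tests of lists held with it. The 24 lists tested were RAS-MAPK output, MYC and ribosome biogenesis, p53 targets, cell cycle and replication, neural stem and radial glia, astrocyte, oligodendrocyte lineage, neuronal, mesenchymal and extracellular matrix, smooth muscle and epithelial, embryonal and pluripotency, Hox genes, growth regulators silenced by Polycomb, Polycomb complex subunits, SWI/SNF subunits, SHH signalling, WNT signalling, BMP and TGF-beta response, hypoxia and glycolysis, interferon response, microglia and macrophage, endothelial and pericyte, ependymal and cilia, and choroid plexus. The smallest list tested needed 4 measured genes. An erythroid list with 2 measured genes was not tested, nor were the list of added oncogenes and a set of X and Y linked genes.

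The position of each array between a parent group and the HRAS+MYC group was its projection on the line between their means over all genes, with an array of either group left out of its own group's mean. Positions were compared with 2-sided exact permutation tests of the difference of means.

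The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, in each comparison, the added oncogenes, the genes with the largest rise and the largest fall among those that passed and whose groups of arrays did not overlap (6 per direction in the first 3 comparisons and 3 in the others), and from each called list the members with the largest change in its direction (3 and 2). Unnamed gene models, receptor families of smell, small RNAs and X and Y linked genes were left out of the rule. In the first 3 comparisons 12 histology markers were added whatever their values. The text names a part of the genes that this rule gives. Neurod1 was named after its values were seen.

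The steps were tested on simulated data, with changes added to 200 of 19938 genes. Likeness to real arrays was not tested. Of genes changed by 0.5, 1 and 2 log2 units, 33.0%, 87.5% and 96.5% passed for HRAS against MYC. For HRAS+Bmi1 against HRAS these shares were 6.5%, 63.0% and 92.5%, and between 3.85% and 8.03% of the calls were unchanged genes. In a simulated shift of the neuronal list by 0.5 that list was called (adjusted p 0.048) with 0 others, and arrays placed at 0, 0.5 and 1 between groups were found at −0.0078, 0.499 and 0.995.

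The alternatives were array weights, a further quantile normalization, the replicate number of the labels as a block, the 13665 genes that were above the array median in at least 2 arrays, a 2-fold threshold, tumour types in place of oncogene groups, the mean of a gene's probe sets, a trended and robust prior, a fit of only the groups compared, positions over only the genes that differ between parent and HRAS+MYC, and leaving out each array in turn. A setting without MYC replicates 4 and 5 was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.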

Results

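Gene expression was measured on Affymetrix Mouse Gene 1.0 ST arrays in 32 neurosphere cultures grown from mouse brain tumours. The tumours had been raised by transplanting into the brain p53-deficient neurosphere cells of the postnatal lateral ventricle wall that carried added oncogenes. Tumour cells that expressed the transgene and its fluorescent marker were isolated by flow cytometry before culture, a gate that would remove host cells without the cassette. HRAS is a small GTPase upstream of the MAP kinase pathway, MYC is a transcription factor that drives growth, and Ezh2 and Bmi1 are subunits of the Polycomb repressive complexes. Glioma cultures came from cells given HRAS (n = 5) or HRAS+Bmi1 (n = 2). Primitive neuroectodermal tumour (PNET) cultures came from cells given MYC (n = 6), MYC+Ezh2 (n = 5) or MYC+Bmi1 (n = 3). Cultures from tumours like atypical teratoid/rhabdoid tumour (AT/RT) came from cells given HRAS+MYC together (n = 7). In a consecutive design, HRAS was added to cells of a PNET (MYC then HRAS, n = 2) or MYC to cells of a glioma (HRAS then MYC, n = 2), and cultures of the secondary tumours were profiled. The labels do not state if replicates came from separate tumours or animals, so p-values measure the spread between arrays. This may be technical, but Xist (3.79 to 11.05) and Eif2s3y (3.81 to 8.57) in MYC argue against that alone. The number of arrays limits precision.

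The first principal component held 42.5% of the variance and the second 14.5%. All 14 arrays of the MYC, MYC+Ezh2 and MYC+Bmi1 groups had positive scores on the first component, and every array of the other groups had a negative score. The second component separated the 7 HRAS and HRAS+Bmi1 arrays, with positive scores, from the 7 HRAS+MYC arrays, with negative scores.

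**Figure D1:**
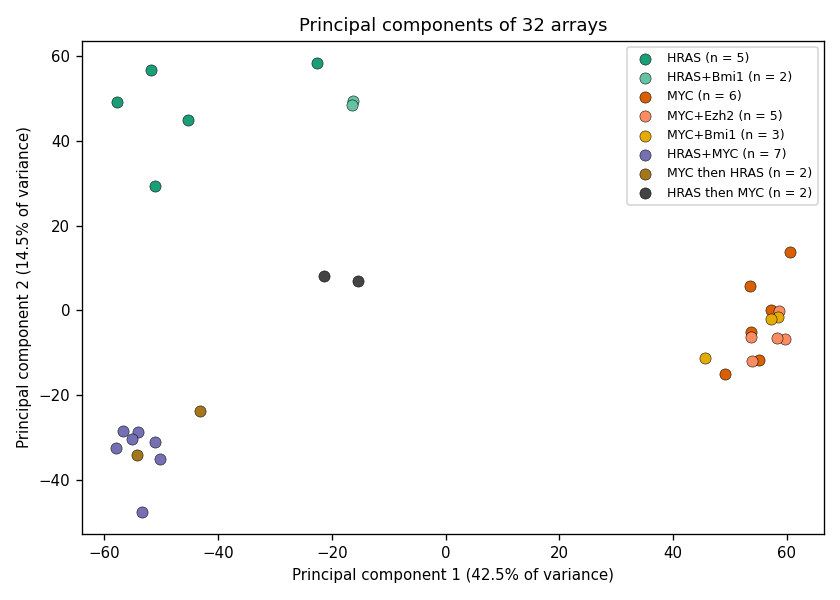
Scores of the 32 arrays on the first (42.5% of variance) and second (14.5%) principal components of the log2 values, in the units of the scores, with 1 point per array coloured by group. The 14 MYC, MYC+Ezh2 and MYC+Bmi1 arrays lie on the right, the 7 HRAS and HRAS+Bmi1 arrays at the upper left and the 7 HRAS+MYC arrays at the lower left.

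Mouse Myc was highest where no MYC had been added, at 11.36 ± 0.995 (log2, SD, n = 5) in HRAS and 10.62 ± 0.345 (SD, n = 2) in HRAS+Bmi1 cells. It stood at 7.00 ± 0.737 (SD, n = 6) in MYC, 6.97 ± 0.366 (n = 5) in MYC+Ezh2, 6.44 ± 0.210 (n = 3) in MYC+Bmi1 and 7.66 ± 0.297 (n = 7) in HRAS+MYC cells. The labels do not give the species or the part of the added MYC sequence, so the mouse Myc probe set does not check the MYC labels. Mouse Ezh2 was 12.16 ± 0.119 (SD, n = 5) in MYC+Ezh2 against 10.52 ± 0.324 (n = 6) in MYC cells. Mouse Bmi1 was 10.13 ± 0.113 (SD, n = 3) in the arrays labelled MYC+Bmi1 against 9.89 ± 0.174 (n = 6) in MYC cells, a difference of 0.24 ± 0.190 (SE) that did not pass (adjusted p 0.668). Bmi1 was 0.89 ± 0.225 (SE) higher in HRAS+Bmi1 than HRAS arrays (adjusted p 0.0152), and 0.58 without HRAS+Bmi1 replicate 1. HRAS replicate 3 (10.23) lay between the HRAS+Bmi1 arrays (10.06 and 10.70). Hras was not analysed here.

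Levels of X and Y linked genes varied between and within groups, and the labels do not give the sex of the cells. Xist, which marks an inactive X, ran from 3.86 to 4.47 in HRAS, 3.79 to 11.05 in MYC, 8.82 to 10.14 in MYC+Ezh2, 3.96 to 6.82 in MYC+Bmi1 and 3.79 to 9.42 in HRAS+MYC arrays. It was 8.33 and 8.38 in MYC then HRAS and 4.29 and 4.55 in HRAS then MYC arrays, where the Y-linked Eif2s3y was 3.98 and 3.82 against 7.55 and 8.18 and Uty 3.90 and 3.48 against 6.11 and 6.07. Of 52 gene tests on Xist, Eif2s3y, Kdm5d and Uty 2 passed, Eif2s3y in HRAS+MYC against HRAS (−2.67, adjusted p 0.00675) and Kdm5d in MYC then HRAS against MYC arrays (−2.55, adjusted p 0.0184, and 0.0945 and 0.165 without either MYC then HRAS array). Sex was not separated from the oncogenes in the comparisons that follow, nor from their order in the secondary tumours.

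**Figure D2:**
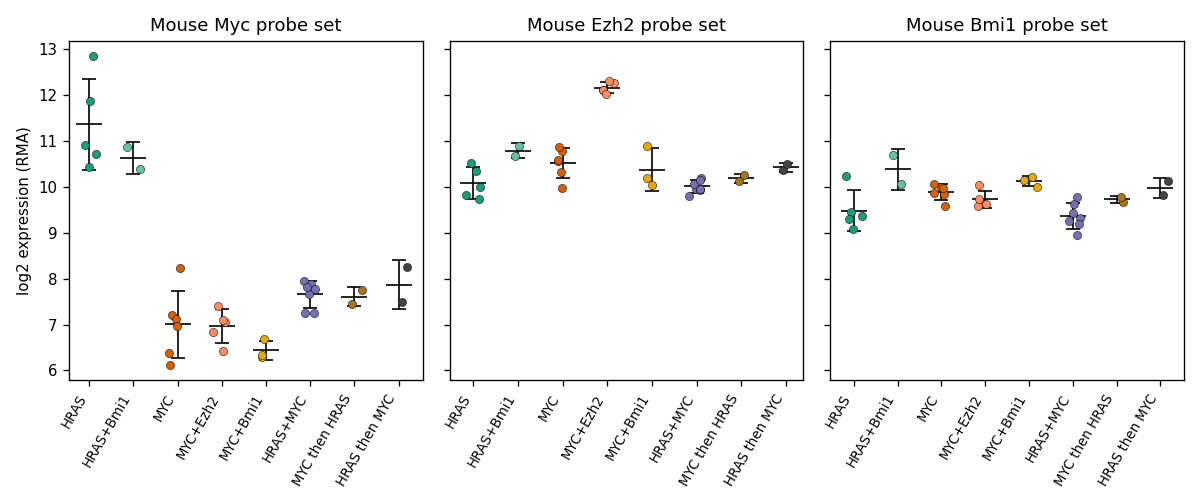
Log2 expression (RMA) of the mouse Myc, Ezh2 and Bmi1 probe sets in the 8 groups, with 1 point per array and bars for the mean and SD. Myc was highest in HRAS arrays.

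The first comparison asked how HRAS glioma cells (n = 5) and MYC PNET cells (n = 6) differed. Among the largest rises in HRAS cells, Anxa1, an annexin that binds membranes, rose by 7.24 ± 0.367 (log2, SE), the calcium-binding protein S100a6 by 6.73 ± 0.206, the urokinase Plau by 6.72 ± 0.318, the alcohol dehydrogenase Adh7 by 6.22 ± 0.419 and the retinoic acid-binding protein Crabp1 by 5.91 ± 0.513. Among the largest falls, the neuronal glycoprotein Gpm6a fell by 6.21 ± 0.703, the neuronal amino acid transporter Slc6a15 by 5.61 ± 0.560, Sncaip, which encodes a partner of alpha-synuclein, by 4.61 ± 0.474, and the G protein subunit Gnai1 by 4.34 ± 0.496. By the rule for naming genes, all 5 HRAS arrays lay on the same side of all 6 MYC arrays for each of them. The largest adjusted p was 8.47e-08. In all, 6655 of 19938 genes passed, 3066 higher and 3589 lower in HRAS cells.

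Of the RAS-MAPK output list, genes induced by or feeding back on this pathway, 18 of 20 members rose in HRAS cells (19 adjusted over the list alone) and 2 did not pass. The AP-1 factor Fosl1 rose by 4.48 ± 0.169 and the MAP kinase phosphatase Dusp4 by 3.89 ± 0.590, and the list was called (adjusted p 6.54e-17). Of the mesenchymal and extracellular matrix list 19 of 23 rose (19 adjusted over the list alone, adjusted p 6.54e-17), and of the BMP and TGF-beta response list 10 rose and 1 fell of 16 (10 and 2 adjusted over the list alone, adjusted p 0.000184). Ltbp1, which binds latent TGF-beta, rose by 5.40 ± 0.403. These 3 calls held with an estimated correlation between genes, at adjusted p = 0.00133, 0.000142 and 0.0160.

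Genes of the MYC and ribosome biogenesis list were lower in HRAS cells, where 21 of 27 fell and 6 did not pass (22 adjusted over the list alone, adjusted p 1.29e-08, and adjusted p = 0.247 with an estimated correlation). Spermidine synthase, Srm, fell by 1.82 ± 0.217 and the pyrimidine enzyme Cad by 1.60 ± 0.192. Of the cell cycle and replication list 10 of 23 fell (10 adjusted over the list alone, adjusted p 0.00922, and adjusted p = 0.503 with an estimated correlation), and the ribonucleotide reductase subunit Rrm2 fell by 1.31 ± 0.238. Of the subunits of the SWI/SNF chromatin remodelling complex 9 of 20 fell (10 adjusted over the list alone, adjusted p 0.000336, and adjusted p = 0.188 with an estimated correlation). Bcl7a fell by 1.88 ± 0.190 and Dpf1 by 1.73 ± 0.128. Mki67, a marker of dividing cells, fell by 1.08 ± 0.256 (adjusted p 0.00136) and mouse Ezh2 by 0.43 ± 0.155 (adjusted p 0.0312), while Bmi1 (−0.40 ± 0.163, adjusted p 0.0574) and the SWI/SNF subunit Smarcb1 (−0.26 ± 0.107, adjusted p 0.0637) did not pass. The Ezh2 call was lost without HRAS replicate 1, 2 or 4 or MYC replicate 1, 3, 4 or 5 (adjusted p 0.0512 to 0.111) and in a fit of these 2 groups alone (adjusted p 0.129). Bmi1 passed without HRAS replicate 3 (adjusted p 0.00159) or MYC replicate 2 (adjusted p 0.0338), and Smarcb1 without HRAS replicate 2 (adjusted p 0.0208) or MYC replicate 6 (adjusted p 0.0246). Without MYC replicates 4 and 5 the cell cycle call was lost (adjusted p 0.108).

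Hypoxia and glycolysis genes rose in 11 and fell in 1 of 15 cases (11 and 1 adjusted over the list alone, adjusted p 8.93e-07, and adjusted p = 0.160 with an estimated correlation). The glucose transporter Slc2a1 rose by 3.46 ± 0.269 and the vasodilator peptide Adm by 3.59 ± 0.436. Interferon response genes rose in 11 of 15 cases (11 adjusted over the list alone, adjusted p 1.78e-06, and adjusted p = 0.191 with an estimated correlation). Ifit1, which binds viral RNA, rose by 3.92 ± 0.383 and the class I histocompatibility chain B2m by 2.72 ± 0.289.

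The neuronal and oligodendrocyte lineage lists were called lower in HRAS cells. Of the neuronal list 12 fell and 3 rose of 26 (18 and 4 adjusted over the list alone, adjusted p 0.00635, and adjusted p = 0.404 with an estimated correlation). The microtubule protein Map2 fell by 4.33 ± 0.560, neuronal tubulin Tubb3 by 2.59 ± 0.443 and the synaptic vesicle protein Syp by 2.39 ± 0.534. Of the oligodendrocyte lineage list 7 of 16 fell (9 adjusted over the list alone, adjusted p 0.00623, and adjusted p = 0.50 with an estimated correlation), and the proteoglycan Bcan fell by 3.22 ± 0.727. The intermediate filament Vim rose by 2.22 ± 0.331. The lineage factor Olig2 (−2.57 ± 1.01, adjusted p 0.0510), Gfap (−0.78 ± 0.483, adjusted p 0.242), S100b (−0.69 ± 0.314, adjusted p 0.0976), the stem cell factor Sox2 (1.86 ± 0.783, adjusted p 0.0695) and smooth muscle actin, Acta2 (0.73 ± 0.408, adjusted p 0.189), did not pass. Single arrays decided some of these calls. Olig2 passed without HRAS replicate 3 (adjusted p 0.0111) or MYC replicate 4 (adjusted p 0.00990) or 5 (adjusted p 0.0113), and S100b without MYC replicate 4 (adjusted p 0.00962) or 5 (adjusted p 0.0265). Sox2 passed without MYC replicate 1, 2, 3 or 6 (adjusted p 0.0221 to 0.0451) and Acta2 without HRAS replicate 5 (adjusted p 0.0323). Nes rose by 0.90 ± 0.250 (adjusted p 0.00549), and by 0.49 without MYC replicates 4 and 5 (adjusted p 0.0764, and 0.0704 in a fit of these 2 groups alone).

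On the HRAS side replicate 3 lay above the other 4 HRAS arrays in Map2 (9.99 against 5.20 to 6.18), Tubb3 (8.08 against 5.72 to 6.31), Gpm6a (7.42 against 4.04 to 4.56) and Bcan (8.73 against 5.37 to 5.86). MYC replicates 4 and 5 stood apart from the other 4 MYC arrays in other genes. Sox2 was 4.84 and 6.62 in them against 10.74 to 11.58 in the others, Olig2 was 5.02 and 5.17 against 9.49 to 10.57, and Neurod1, a factor of neuronal differentiation, was 10.55 and 10.83 against 3.39 to 3.85. The median member of the oligodendrocyte lineage list lay −2.06 and −1.57 from the MYC median in these arrays, that of the neural stem and radial glia list −1.20 and −0.69, that of the astrocyte list −0.97 and −0.98, and that of the neuronal list 0.56 and 0.84. With both left out, Olig2 stood at −4.25 between HRAS and MYC cells (adjusted p 0.000323), S100b at −1.26 (adjusted p 0.000157) and Gfap at −1.30 (adjusted p 0.0460), and the astrocyte list was called lower (adjusted p 0.00123).

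The remaining lists were not called between HRAS and MYC cells. The adjusted p was 0.0537 for smooth muscle and epithelial genes, 0.0771 for astrocyte genes, 0.0771 for SHH signalling, 0.0931 for endothelial cells and pericytes, 0.115 for growth regulators silenced by Polycomb, 0.464 for p53 targets, WNT signalling and choroid plexus, 0.565 for Polycomb complex subunits and 0.716 for Hox genes. It was 0.882 for microglia and macrophages, 0.921 for neural stem and radial glia, and 0.932 for embryonal and pluripotency genes and for ependymal cells and cilia. The median and the mean differed in sign for the microglia list (−0.00 and 0.30), the neural stem list (0.04 and −0.10) and the embryonal list (−0.11 and 0.18). For every list called in any of the 13 comparisons they had the sign of the test. The smooth muscle and epithelial list was called when HRAS replicate 3, 4 or 5 or MYC replicate 5 or 6 was left out (adjusted p 0.0270 to 0.0474), and the astrocyte list without MYC replicate 4 (adjusted p 0.0258) or 5 (adjusted p 0.0164). The SHH signalling list was called without MYC replicate 4 (adjusted p 0.0495) and the endothelial and pericyte list without HRAS replicate 4 (adjusted p 0.0477).

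**Figure D3:**
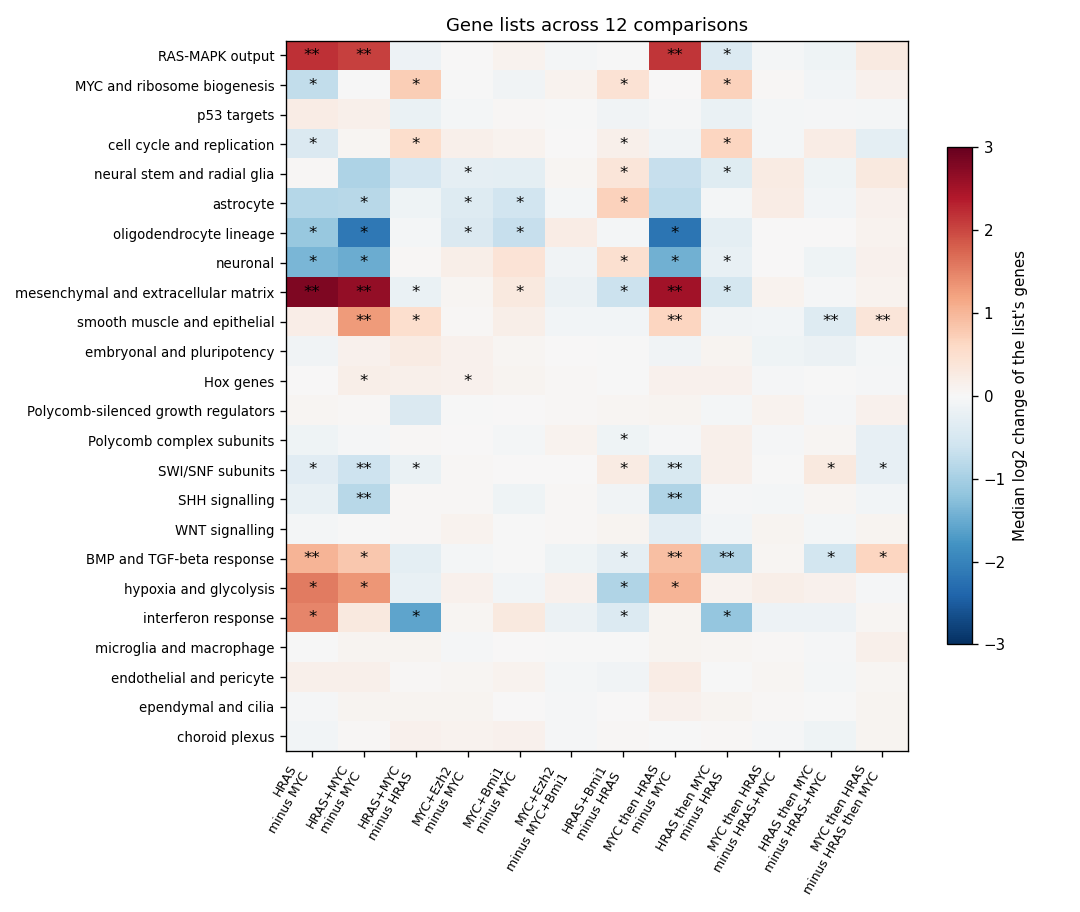
Median log2 change of the measured genes of each of 24 lists (vertical axis) in 12 comparisons (horizontal axis), red where the first group named was higher and blue where it was lower. A single asterisk marks a list called with the preset correlation, and a double asterisk a list also called with an estimated correlation. The mesenchymal list reaches a median of 2.81 between HRAS and MYC cells.

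The second comparison set HRAS+MYC cells of AT/RT-like tumours (n = 7) against MYC cells (n = 6), which differ in added HRAS. Among the largest rises, the prostaglandin synthase Ptgs2 rose by 7.14 ± 0.333 (log2, SE), the interleukin receptor chain Il5ra by 6.88 ± 0.113, keratin 19 (gene symbol Krt19) by 6.72 ± 0.261, the membrane protein Dynap by 6.40 ± 0.295 and Anxa1 by 7.67 ± 0.337. Gpm6a fell by 6.63 ± 0.646, the tetraspanin Tspan6 by 6.02 ± 0.463, Map2 by 5.52 ± 0.515 and Marcks, a substrate of protein kinase C, by 5.48 ± 0.511. By the same rule, all 7 HRAS+MYC arrays lay on the same side of all 6 MYC arrays for each of these genes. Their largest adjusted p was 3.87e-09. In all, 6818 genes passed, 3141 higher and 3677 lower in HRAS+MYC cells.

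The RAS-MAPK output list again lay higher with HRAS, with 16 of 20 members up (17 and 1 down adjusted over the list alone, adjusted p 6.37e-13, and adjusted p = 0.00537 with an estimated correlation). The EGF receptor ligand Ereg rose by 6.19 ± 0.215 and the urokinase receptor Plaur by 4.51 ± 0.295. Mesenchymal genes rose in 16 of 23 cases (16 up and 1 down adjusted over the list alone, adjusted p 1.53e-11, and adjusted p = 0.00201 with an estimated correlation). Of the smooth muscle and epithelial list 12 rose and 1 fell of 18 (12 and 1 adjusted over the list alone, adjusted p 1.57e-07, and adjusted p = 0.00978 with an estimated correlation). The simple epithelial keratins Krt18 and Krt8 rose by 5.95 ± 0.566 and 5.34 ± 0.234, while Acta2 was at −0.63 ± 0.375 (adjusted p 0.206).

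Of the SWI/SNF subunits 15 of 20 fell in HRAS+MYC cells (16 adjusted over the list alone, adjusted p 9.77e-09, and adjusted p = 0.0140 with an estimated correlation). Bcl7a fell by 2.54 ± 0.175 and the ATPase Smarca2 by 2.50 ± 0.223. Smarcb1, the subunit whose loss marks human AT/RT, fell by 0.52 ± 0.098 (adjusted p 0.000111), from 10.43 ± 0.187 (SD, n = 6) to 9.90 ± 0.0991 (n = 7). Of the SHH signalling list 7 of 11 fell (7 adjusted over the list alone, adjusted p 0.0133, and adjusted p = 0.0498 with an estimated correlation), and the co-receptors Gas1 and Boc fell by 1.87 ± 0.281 and 1.53 ± 0.207. Mouse Ezh2 fell by 0.51 ± 0.142 (adjusted p 0.00601, and 0.0506 without MYC replicates 4 and 5) and Bmi1 by 0.53 ± 0.150 (adjusted p 0.00677). The mouse Myc difference of 0.66 ± 0.311 did not pass (adjusted p 0.107), and passed without MYC replicate 6 (adjusted p 0.0194).

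The neuronal and 2 glial lists were called lower in HRAS+MYC cells. Of the neuronal list 14 fell and 2 rose of 26 (18 and 2 adjusted over the list alone, adjusted p 3.23e-05, and adjusted p = 0.169 with an estimated correlation). The RNA-binding protein Elavl4 fell by 3.05 ± 0.334, Syp by 2.23 ± 0.490 and Tubb3 by 1.92 ± 0.407. Of the oligodendrocyte lineage list 11 of 16 fell (13 adjusted over the list alone, adjusted p 0.000167, and adjusted p = 0.484 with an estimated correlation). Olig2 fell by 3.51 ± 0.928 and Bcan by 3.89 ± 0.668. Of the astrocyte list 9 fell and 3 rose of 16 (9 and 3 adjusted over the list alone, adjusted p 0.0133, and adjusted p = 0.550 with an estimated correlation). The glutamate transporter Slc1a3 fell by 4.81 ± 0.521 and Vim rose by 1.73 ± 0.305. S100b fell by 0.83 ± 0.289 (adjusted p 0.0255), a call lost without HRAS+MYC replicate 5 or MYC replicate 1, 2 or 6 (adjusted p 0.0516 to 0.0896) or in a fit of these groups alone (adjusted p 0.108), and Gfap and Nes did not pass. The astrocyte call was lost without MYC replicate 6 (adjusted p 0.0954), the array with Gfap at 9.08 against 4.71 to 5.83 in the other MYC arrays. MYC replicates 4 and 5, low in Sox2 (4.84 and 6.62) and Olig2 (5.02 and 5.17), belong to the MYC side of these differences. Sox2 was 1.02 ± 0.720 higher in HRAS+MYC cells (adjusted p 0.296), and with replicates 4 and 5 left out its difference turned to −0.80 (adjusted p 0.0133). The neural stem and radial glia list was then called lower (adjusted p 0.00233).

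Hypoxia and glycolysis genes rose in 12 and fell in 1 of 15 cases (12 and 1 adjusted over the list alone, adjusted p 7.45e-06, and adjusted p = 0.141 with an estimated correlation), and Slc2a1 rose by 3.23 ± 0.247. BMP and TGF-beta response genes rose in 9 and fell in 4 of 16 cases (9 and 4 adjusted over the list alone, adjusted p 0.0133, and adjusted p = 0.107 with an estimated correlation). Transforming growth factor beta, Tgfb1, rose by 4.30 ± 0.256. Of the Hox genes 5 of 22 rose (5 adjusted over the list alone, adjusted p 0.0442, and adjusted p = 0.550 with an estimated correlation), and Hoxc6 rose by 0.43 ± 0.105. Without MYC replicates 4 and 5 the BMP and TGF-beta (adjusted p 0.0640) and Hox (adjusted p 0.127) calls were lost, and the Hox call was also lost without MYC replicate 4 or 5 or HRAS+MYC replicate 3, 4 or 6 (adjusted p 0.0555 to 0.0792) and with dim genes left out (adjusted p 0.108). Mki67 fell by 0.82 ± 0.235 (adjusted p 0.00735), and by 0.64 without MYC replicates 4 and 5 (adjusted p 0.0632). The MYC and ribosome biogenesis list, with 2 of 27 members up, was not called (adjusted p 0.823), and its median and mean differed in sign (−0.01 and 0.07).

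The third comparison set HRAS+MYC cells (n = 7) against HRAS glioma cells (n = 5), which differ in added MYC. Il5ra was higher by 6.83 ± 0.119 (log2, SE), Krt19 by 6.31 ± 0.275, Dynap by 5.58 ± 0.310, the annexin Anxa8 by 4.99 ± 0.351 and the water channel Aqp8 by 4.85 ± 0.241. Of extracellular matrix genes, the laminin chain Lama4 fell by 5.55 ± 0.240, fibronectin, Fn1, by 4.85 ± 0.444, and tenascin C, Tnc, by 4.71 ± 0.536. The WNT pathway modulator Dkk2 fell by 5.03 ± 0.251 and mouse Myc by 3.70 ± 0.327. By the same rule, every HRAS+MYC array lay on the same side of every HRAS array for the 6 largest rises and 6 largest falls. In all, 4921 genes passed, 2325 higher and 2596 lower in HRAS+MYC cells.

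Of the MYC and ribosome biogenesis list 25 of 27 rose with added MYC (25 adjusted over the list alone, adjusted p 2.21e-14, and adjusted p = 0.203 with an estimated correlation). Srm rose by 1.51 ± 0.210 and Cad by 1.31 ± 0.186. Of the cell cycle and replication list 7 of 23 rose (10 adjusted over the list alone, adjusted p 0.000173, and adjusted p = 0.558 with an estimated correlation). Rrm2 rose by 1.68 ± 0.231 and the mitotic activator Cdc20 by 0.84 ± 0.193. Interferon response genes fell in 12 of 15 cases (13 adjusted over the list alone, adjusted p 4.93e-08, and adjusted p = 0.203 with an estimated correlation). Ifit1 fell by 3.22 ± 0.371 and Ifit2 by 2.78 ± 0.400. Of the smooth muscle and epithelial list 10 rose and 2 fell of 18 (10 and 3 adjusted over the list alone, adjusted p 0.000152, and adjusted p = 0.203 with an estimated correlation). Krt8 rose by 4.75 ± 0.247 and the desmosome protein Dsp by 3.59 ± 0.312.

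Mesenchymal genes fell in 8 and rose in 1 of 23 cases (8 and 1 adjusted over the list alone, adjusted p 0.0183, and adjusted p = 0.343 with an estimated correlation). The matrix protein Sparc fell by 2.26 ± 0.535 and Tgfbi by 2.12 ± 0.362. Of the SWI/SNF subunits 6 fell and 1 rose of 20 (7 and 1 adjusted over the list alone, adjusted p 0.0170, and adjusted p = 0.462 with an estimated correlation). Smarca2 fell by 2.04 ± 0.235. Both calls were lost when dim genes were left out (adjusted p 0.0908 for each). Nes fell by 0.92 ± 0.242 (adjusted p 0.00564). Acta2 fell by 1.36 ± 0.394 (adjusted p 0.0117), with adjusted p 0.0650 without HRAS replicate 4 and 0.0579 in a fit of these groups alone. Olig2, Gfap, S100b, Sox2, Tubb3, Map2, Syp, Vim, Mki67 and Smarcb1 did not pass. In a fit of these groups alone Sox2 (adjusted p 0.0187) and Vim (adjusted p 0.00107) passed, and Smarcb1 (−0.26, adjusted p 0.0631) passed without HRAS+MYC replicate 1 (adjusted p 0.0491) or HRAS replicate 5 (adjusted p 0.0468). The neural stem list was called only when HRAS replicate 5 was left out (adjusted p 0.0380).

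Added Ezh2 was examined in MYC+Ezh2 (n = 5) against MYC cells (n = 6). Ezh2 itself rose by 1.64 ± 0.155 (log2, SE, adjusted p 7.96e-07). The receptor tyrosine kinase Ror2 rose by 1.42 ± 0.172 (adjusted p 7.04e-05) and the galectin Lgals1 by 1.06 ± 0.193 (adjusted p 0.0225). The phosphodiesterase Pde1b fell by 2.36 ± 0.423 (adjusted p 0.0219), the Ras family exchange factor Rasgef1b by 2.05 ± 0.420 (adjusted p 0.0341) and the transcription factor Zbtb20 by 1.97 ± 0.413 (adjusted p 0.0341). Of these genes only Ezh2 and Ror2 passed with any 1 array left out; without MYC+Ezh2 replicate 3 or 5 the others had adjusted p 0.0605 to 0.155. In all, 49 genes passed, 26 higher and 23 lower, and 29 higher and 15 lower after a further quantile normalization. The count was 202 without MYC replicates 4 and 5, 9 with a replicate block and 1, Ezh2, in a fit of these 2 groups alone. Leaving out MYC+Ezh2 replicate 1 gave 233 genes, replicate 2 gave 16, replicate 3 gave 4, replicate 4 gave 8 and replicate 5 gave 6, and leaving out MYC replicate 1 gave 17, replicate 2 gave 15, replicate 3 gave 80, replicate 4 gave 18 and replicate 5 gave 14.

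Glial lists lay lower in MYC+Ezh2 cells. Of the astrocyte list 1 of 16 fell (3 down and 1 up adjusted over the list alone, adjusted p 0.000370, and adjusted p = 0.925 with an estimated correlation). That member, the glutamate transporter Slc1a2, fell by 1.09 ± 0.237 (adjusted p 0.0452). No member passed over all genes in the oligodendrocyte lineage list (0 adjusted over the list alone, adjusted p 0.00592, median −0.44), the neural stem and radial glia list (1 down adjusted over the list alone, adjusted p 0.0358, median −0.27) or the Hox list, which was called higher (2 up adjusted over the list alone, adjusted p 0.00592, median 0.12). Each of these 3 calls was lost, at adjusted p = 0.925 with an estimated correlation. In MYC replicates 4 and 5 the median oligodendrocyte list member lay −2.06 and −1.57 from the MYC median, and Gfap was 9.08 in MYC replicate 6. Without replicate 6 the astrocyte (adjusted p 0.0816), oligodendrocyte (adjusted p 0.0816) and neural stem (adjusted p 0.421) calls were lost. Leaving out MYC+Ezh2 replicate 3 or 5 or MYC replicate 1 or 2 also ended the oligodendrocyte call (adjusted p 0.0857 to 0.295), and leaving out any of these or MYC replicate 3 the neural stem call (adjusted p 0.0857 to 0.249), which was also lost with dim genes left out (adjusted p 0.150). With MYC replicates 4 and 5 both left out, the neuronal (adjusted p 0.00218) and cell cycle (adjusted p 0.00178) lists were called. The neuronal list was also called without MYC+Ezh2 replicate 1 (adjusted p 0.0367) and the cell cycle list without MYC replicate 4 (adjusted p 0.0383). The growth regulators silenced by Polycomb, with 0 of 18 members past the threshold, were not called (adjusted p 0.990).

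Added Bmi1 was examined in the arrays labelled MYC+Bmi1 (n = 3) against MYC cells (n = 6). The laminin chain Lamb1 rose by 2.36 ± 0.447 (log2, SE, adjusted p 0.0212), Lgals1 by 1.56 ± 0.226 (adjusted p 0.00205) and Edaradd, an adaptor of the ectodysplasin receptor, by 1.48 ± 0.245 (adjusted p 0.00752). The teneurin Tenm3 fell by 2.39 ± 0.279 (adjusted p 6.52e-05), the zinc finger factor Zfp521 by 2.69 ± 0.573 (adjusted p 0.0456) and Pcolce2, which aids collagen processing, by 2.57 ± 0.526 (adjusted p 0.0373). Lgals1 and Tenm3 passed with any 1 array left out, while without MYC+Bmi1 replicate 3 Lamb1 (adjusted p 0.210), Edaradd (adjusted p 0.102), Zfp521 (adjusted p 0.192) and Pcolce2 (adjusted p 0.102) did not. Without its replicate 2 Lamb1 (adjusted p 0.0847), Pcolce2 (adjusted p 0.172) and Zfp521 (adjusted p 0.252) did not pass, and without MYC replicate 1, 2 or 3 the last pair had adjusted p 0.0673 to 0.0863, with Zfp521 at 0.0552 without MYC replicate 5. In all, 30 genes passed, 20 higher and 10 lower. The count was 234 without MYC+Bmi1 replicate 1, 9 without its replicate 3, 17 without MYC replicate 1, 51 without MYC replicate 4, 84 without MYC replicate 6, 245 without MYC replicates 4 and 5, and 1 in a fit of these 2 groups alone.

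The mesenchymal list was called higher in MYC+Bmi1 cells, with 1 of 23 members up (1 adjusted over the list alone, adjusted p 0.0156, and adjusted p = 0.812 with an estimated correlation). The astrocyte and oligodendrocyte lineage lists were called lower with 0 of 16 members past the threshold in each (0 adjusted over the list alone, adjusted p 0.0156 for both, and adjusted p = 0.842 with an estimated correlation for both). The mesenchymal call was lost without MYC+Bmi1 replicate 3 (adjusted p 0.457) or MYC replicate 1 (adjusted p 0.0656) or 2 (adjusted p 0.0509). The astrocyte call was lost without MYC+Bmi1 replicate 2 (adjusted p 0.218) or MYC replicate 2 (adjusted p 0.0509) or 6 (adjusted p 0.293), and the oligodendrocyte call without MYC+Bmi1 replicate 2 or 3 or MYC replicate 1, 2 or 6 (adjusted p 0.0887 to 0.433). With MYC replicates 4 and 5 both left out, the neural stem list was called lower (adjusted p 3.17e-08) and the neuronal (adjusted p 5.29e-05) and cell cycle (adjusted p 0.00897) lists higher. The MYC side of the glial difference again held replicates 4 and 5, with Olig2 at 5.02 and 5.17, and replicate 6, with Gfap at 9.08. Between MYC+Ezh2 and MYC+Bmi1 cells 1 gene passed in limma, Ezh2, higher by 1.79 ± 0.187 in MYC+Ezh2 cells (adjusted p 7.42e-06), and 831 genes had an unadjusted p below 0.05. Without MYC+Ezh2 replicate 2 that count was 2, and without MYC+Bmi1 replicate 1, 2 or 3 it was 11, 7 or 3. No list was called between these groups.

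Bmi1 was also added to HRAS cells, in HRAS+Bmi1 (n = 2) against HRAS cells (n = 5). The calcium buffer calbindin, Calb1, rose by 5.79 ± 0.302 (log2, SE), Pcp4l1 by 5.20 ± 0.744, the solute carrier Slc35f1 by 4.25 ± 0.367 and the stem cell marker Prom1 by 3.30 ± 0.574. The peptidase inhibitor Pi15 fell by 5.01 ± 0.476, the cornified envelope protein Sprr1a by 3.86 ± 0.665, the ion transport regulator Fxyd5 by 3.80 ± 0.421 and S100a6 by 1.85 ± 0.285. Each had an adjusted p of 0.000582 or lower. In all, 1178 genes passed (572 higher, 606 lower), and 533 in a fit of these 2 groups alone. Leaving out 1 array gave most without HRAS replicate 3 (1801) and fewest without HRAS+Bmi1 replicate 1. Both HRAS+Bmi1 arrays shared shifts on chromosomes 4 and 16, and a single origin was not tested.

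Neural and other lists lay higher in HRAS+Bmi1 than HRAS cells, in 6 calls all lost with an estimated correlation. The astrocyte list had 3 of 16 up (6 adjusted over the list alone, adjusted p 0.00180, and 0.466 estimated), and apolipoprotein E, Apoe, rose by 2.77 ± 0.743 and clusterin, Clu, by 2.53 ± 0.537. The neural stem list had 4 of 19 up (4 adjusted over the list alone, adjusted p 0.0200, and 0.466 estimated) and the neuronal list 2 of 26 (3 adjusted over the list alone, adjusted p 0.0446, and 0.605 estimated), with the interneuron factor Dlx1 up by 3.51 ± 0.707. The SWI/SNF subunits had 3 of 20 up (4 adjusted over the list alone, adjusted p 0.00180, and 0.347 estimated), with Smarcd3 up by 2.10 ± 0.350, the cell cycle list 3 of 23 (4 adjusted over the list alone, adjusted p 0.0482, and 0.795 estimated) and the MYC and ribosome biogenesis list 1 of 27 (12 adjusted over the list alone, adjusted p 7.34e-06, and 0.466 estimated). Without HRAS+Bmi1 replicate 1 the adjusted p was 0.250 for Apoe, 0.140 for Clu and 0.0943 for Dlx1, and Apoe had 0.197 without replicate 2. Without either HRAS+Bmi1 array or HRAS replicate 2, 4 or 5 the neuronal call was lost (adjusted p 0.0533 to 0.0776), and without any of these or HRAS replicate 1 the cell cycle call (adjusted p 0.0533 to 0.161). With dim genes left out the neural stem (adjusted p 0.0545), neuronal (adjusted p 0.0936) and cell cycle (adjusted p 0.115) calls were lost.

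Other lists lay lower in HRAS+Bmi1 cells, in 5 calls that were all lost with an estimated correlation. The mesenchymal list had 3 of 23 down (4 adjusted over the list alone, adjusted p 0.00105, and 0.347 estimated), the hypoxia and glycolysis list 4 down and 1 up of 15 (6 and 1 adjusted over the list alone, adjusted p 0.00180, and 0.466 estimated), and the BMP and TGF-beta response list 3 of 16 down (5 adjusted over the list alone, adjusted p 0.0446, and 0.347 estimated), where the inhibitory Smad7 fell by 1.67 ± 0.386. The Polycomb complex subunits had 2 of 20 down (5 adjusted over the list alone, adjusted p 0.0344, and 0.347 estimated), where Ezh1 fell by 1.38 ± 0.267, and the interferon list 0 of 15 (0 adjusted over the list alone, adjusted p 0.0482, and 0.714 estimated). The hypoxia call was also lost without HRAS+Bmi1 replicate 1 (adjusted p 0.435). Smad7 had adjusted p 0.130 and 0.123 without either HRAS+Bmi1 array and Ezh1 0.0617 without replicate 1, and neither passed in a fit of these 2 groups alone (adjusted p 0.0816 and 0.0703). The BMP and TGF-beta call was lost without HRAS+Bmi1 replicate 1 or HRAS replicate 1, 3 or 4 (adjusted p 0.0580 to 0.0953) and the interferon call without HRAS+Bmi1 replicate 2 or HRAS replicate 1, 3 or 4 (adjusted p 0.160 to 0.333). With dim genes left out the Polycomb (adjusted p 0.0545), BMP and TGF-beta (adjusted p 0.0569) and interferon (adjusted p 0.143) calls were lost. Mouse Ezh2 rose by 0.70 ± 0.214 (adjusted p 0.0491), a call lost without either HRAS+Bmi1 array (adjusted p 0.497 and 0.180) or HRAS replicate 1, 2 or 4 (adjusted p 0.0741 to 0.110).

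Whether arrays labelled with Bmi1 differed alike from their parents was tested as the difference of these effects between MYC and HRAS cells. The effects differed for 485 genes, 219 more positive and 266 more negative in MYC cells. Calb1 differed by −5.49 ± 0.395 (log2, SE, adjusted p 1.63e-09). Pi15, too low in MYC arrays (3.34 to 3.82) to fall much, differed by 5.08 ± 0.623 (adjusted p 1.85e-05). The adhesion receptor Adgrb3 differed by −5.21 ± 0.948 (adjusted p 0.00237). The GABA enzyme Gad2 differed by 4.56 ± 0.882 (adjusted p 0.00450, and 0.0618 in a fit of the 4 groups alone). The effects differed on 5 lists, all lost with an estimated correlation. They were more negative in MYC cells for the MYC and ribosome biogenesis list (1 of 27 members, 1 adjusted over the list alone, adjusted p 7.17e-07, and adjusted p = 0.413 with an estimated correlation), the astrocyte list (4 of 16, and 6 with 1 in the other direction adjusted over the list alone, adjusted p 1.57e-05, and 0.338 estimated), the neural stem list (1 of 19, 1 adjusted over the list alone, adjusted p 0.000887, and 0.338 estimated) and the SWI/SNF list (2 of 20, 4 adjusted over the list alone, adjusted p 0.00561, and 0.338 estimated). They were more positive for the mesenchymal list (3 of 23, 4 adjusted over the list alone, adjusted p 6.50e-06, and 0.0664 estimated). The SWI/SNF call was also lost without MYC replicates 4 and 5 (adjusted p 0.0933). When single arrays were left out, further lists were called. They were hypoxia and glycolysis (without MYC+Bmi1 replicate 2, HRAS+Bmi1 replicate 2, HRAS replicate 1 or 4 or MYC replicate 3, 4 or 5, adjusted p 0.000125 to 0.0485), interferon (without MYC+Bmi1 replicate 2, HRAS+Bmi1 replicate 1, HRAS replicate 2 or 5 or MYC replicate 6, adjusted p 0.000498 to 0.0461), oligodendrocyte (without MYC+Bmi1 replicate 1 or MYC replicate 4 or 5, adjusted p 0.00377 to 0.0165), RAS-MAPK output (without HRAS replicate 4 or MYC replicate 3 or 5, adjusted p 0.0133 to 0.0313), BMP and TGF-beta (without HRAS replicate 5 or MYC+Bmi1 replicate 2, adjusted p 0.0254 and 0.0329) and cell cycle (without MYC replicate 6, adjusted p 0.0461). The count was 202 without MYC+Bmi1 replicate 3, 98 without HRAS+Bmi1 replicate 1, 126 without its replicate 2, 1099 without HRAS replicate 3, 736 without MYC replicate 6, 745 without MYC replicates 4 and 5 and 135 in a fit of the 4 groups alone. The effect on Bmi1 itself did not differ between backgrounds past the threshold (−0.66 ± 0.295, adjusted p 0.253, and 0.0409 without HRAS replicate 3).

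The consecutive design asked where cells lie that received the second oncogene after the first had formed a tumour. On a scale over all genes from 0 at the mean of the parent group to 1 at the mean of the HRAS+MYC group, the MYC then HRAS arrays lay at 0.866 and 0.973, against 0.0574 ± 0.0558 (SD, n = 6) for MYC and 0.979 ± 0.0331 (n = 7) for HRAS+MYC arrays. The difference from MYC arrays was 0.862 (2-sided exact permutation test, p = 0.0357, the smallest that 28 splits allow) and that from HRAS+MYC arrays was −0.0591 (exact p = 0.167). The HRAS then MYC arrays lay at 0.450 and 0.453, against 0.0989 ± 0.123 (SD, n = 5) for HRAS and 0.961 ± 0.0801 (n = 7) for HRAS+MYC arrays. They differed by 0.353 from HRAS and −0.510 from HRAS+MYC arrays (exact p 0.0476 and 0.0278, the smallest that 21 and 36 splits allow). Off the line they lay by 0.503 and 0.576, against 0.320 to 0.552 for HRAS and 0.237 to 0.412 for HRAS+MYC arrays. With a secondary array left out, no exact p below 0.05 can be reached. The p between HRAS then MYC and HRAS arrays was 0.0667 when any 1 HRAS array was left out, and that between MYC then HRAS and MYC arrays was 0.0667 without MYC replicates 4 and 5 (difference 0.875).

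**Figure D4:**
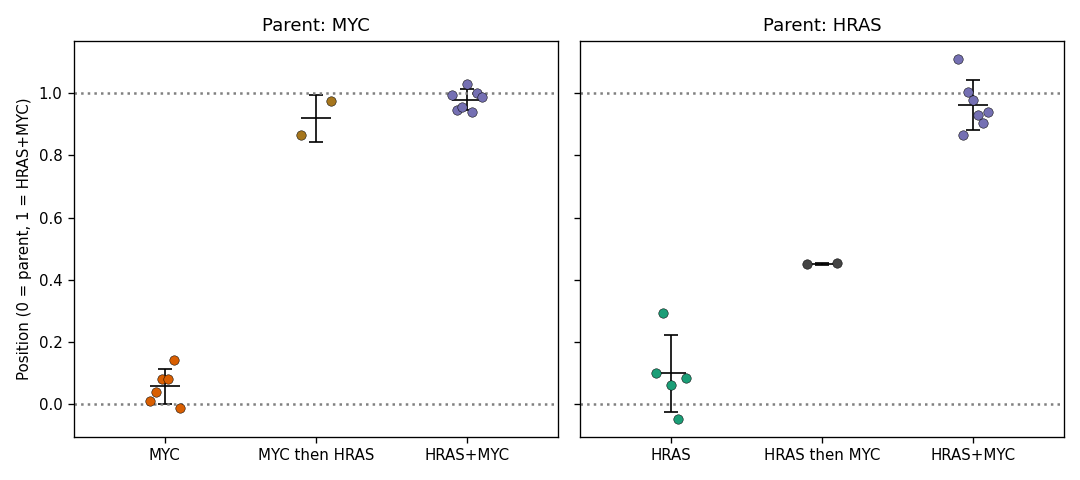
Position of single arrays on the line from the parent mean (0) to the HRAS+MYC mean (1) over all genes, for the MYC parent (left) and the HRAS parent (right), with bars for the mean and SD of each group. MYC then HRAS arrays lie at 0.866 and 0.973 and HRAS then MYC arrays at 0.450 and 0.453.

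In MYC then HRAS cells (n = 2) compared with MYC cells (n = 6), Anxa1 rose by 7.92 ± 0.495 (log2, SE), Il5ra by 7.23 ± 0.165, S100a6 by 6.86 ± 0.278, Krt18 by 6.32 ± 0.831 and Krt8 by 6.02 ± 0.344. Gpm6a fell by 6.26 ± 0.948 and Map2 by 4.83 ± 0.755. All of these had an adjusted p of 2.78e-05 or lower. The RAS-MAPK output list had 15 of 20 members up (16 adjusted over the list alone, adjusted p 7.20e-14, and 0.00369 with an estimated correlation) and the mesenchymal list 14 of 23 (14 adjusted over the list alone, adjusted p 1.70e-12, and 0.00121 with an estimated correlation). The smooth muscle and epithelial list had 8 of 18 (10 up and 1 down adjusted over the list alone, adjusted p 5.75e-07, and 0.0143 with an estimated correlation). SWI/SNF subunits fell in 10 of 20 cases (14 adjusted over the list alone, adjusted p 3.23e-08, and 0.0183 with an estimated correlation), where Smarca2 fell by 2.16 ± 0.327. SHH signalling genes fell in 5 of 11 (5 adjusted over the list alone, adjusted p 0.00410, and 0.0197 with an estimated correlation), where Boc fell by 1.66 ± 0.304. BMP and TGF-beta response genes rose in 6 of 16 cases (8 up and 2 down adjusted over the list alone, adjusted p 0.00354, and 0.0436 with an estimated correlation).

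Neuronal genes fell in 9 and rose in 1 of 26 cases in MYC then HRAS cells (10 and 1 adjusted over the list alone, adjusted p 0.000210, and adjusted p = 0.246 with an estimated correlation). Oligodendrocyte genes fell in 4 of 16 (7 adjusted over the list alone, adjusted p 0.00126, and adjusted p = 0.567 with an estimated correlation), and hypoxia and glycolysis genes rose in 10 and fell in 1 of 15 (11 and 1 adjusted over the list alone, adjusted p 3.23e-06, and adjusted p = 0.121 with an estimated correlation). The astrocyte list was called lower only without MYC replicate 4 or 5 or MYC then HRAS replicate 1 (adjusted p 0.0146 to 0.0278). In all, 4074 genes passed against MYC cells, 1959 higher and 2115 lower, with 2543 without MYC then HRAS replicate 1, 1900 without its replicate 2 and 2367 in a fit of these 2 groups alone. Against HRAS+MYC cells 22 genes passed, 14 higher and 8 lower, and 1470 had an unadjusted p below 0.05. The protocadherin Pcdh7 fell by 3.40 ± 0.482 (adjusted p 0.000898, and 0.0551 without MYC then HRAS replicate 1) and the arginine deiminase Padi4 rose by 2.48 ± 0.409 (adjusted p 0.00587, and 0.208 and 0.0587 without either MYC then HRAS array). That count was 43 without HRAS+MYC replicate 1 and 40 without its replicate 2, and no list was called. Without MYC then HRAS replicate 2 the neural stem (adjusted p 0.0314), astrocyte (adjusted p 0.0272) and hypoxia (adjusted p 0.0388) lists were called.

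In HRAS then MYC cells (n = 2) compared with HRAS cells (n = 5), Cytip, a regulator of immune cell adhesion, rose by 4.81 ± 0.529 (log2, SE) and Rrm2 by 1.97 ± 0.329. Dkk2 fell by 4.79 ± 0.359, Pi15 by 4.70 ± 0.476, the adhesion molecule Ceacam1 by 4.57 ± 0.685, Tgfbi by 4.44 ± 0.517, Tnc by 4.37 ± 0.766 and mouse Myc by 3.49 ± 0.467. Each had an adjusted p of 0.000343 or lower and passed with any 1 array left out. BMP and TGF-beta response genes fell in 8 of 16 cases (10 down and 1 up adjusted over the list alone, adjusted p 3.32e-05, and 0.0177 with an estimated correlation), and Ltbp1 fell by 3.59 ± 0.557. The MYC and ribosome biogenesis list had 14 of 27 up (17 adjusted over the list alone, adjusted p 1.60e-10, and adjusted p = 0.454 with an estimated correlation) and the cell cycle list 7 of 23 up (10 adjusted over the list alone, adjusted p 2.36e-06, and 0.454 estimated). The interferon list had 8 of 15 down (10 adjusted over the list alone, adjusted p 4.14e-07, and 0.454 estimated), where Ifit1 fell by 3.82 ± 0.530.

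Smaller list differences between HRAS then MYC and HRAS cells were all called lower, and lost with an estimated correlation. The RAS-MAPK output list had 4 down and 1 up of 20 (6 and 1 adjusted over the list alone, adjusted p 0.010, and adjusted p = 0.454 with an estimated correlation), where the EGF receptor ligand Hbegf fell by 2.61 ± 0.396. The mesenchymal list had 5 down and 2 up of 23 (7 and 2 adjusted over the list alone, adjusted p 0.0288, and 0.454 estimated), the neural stem list 4 of 19 down (5 adjusted over the list alone, adjusted p 0.0288, and 0.534 estimated) and the neuronal list 3 of 26 down (3 adjusted over the list alone, adjusted p 0.0366, and 0.571 estimated). In the same order they were lost without HRAS then MYC replicate 2, at adjusted p 0.0659, 0.232, 0.0847 and 0.0970. The neuronal call was also lost without HRAS replicate 1 (adjusted p 0.0506) or 3 (adjusted p 0.137), the neural stem call without HRAS replicate 3 (adjusted p 0.0893) and the mesenchymal call without HRAS replicate 1 (adjusted p 0.0506). With dim genes left out all 4 were lost (adjusted p 0.0538, 0.0839, 0.101 and 0.131). In all, 2495 genes passed against HRAS cells, 1256 higher and 1239 lower, with 1110 without HRAS then MYC replicate 1, 544 without its replicate 2 and 983 in a fit of these 2 groups alone.

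Against HRAS+MYC cells, epithelial genes were lower in HRAS then MYC cells. Krt19 fell by 6.82 ± 0.376 (log2, SE), at 5.10 ± 0.0051 (SD, n = 2) against 11.92 ± 0.842 (n = 7), Il5ra fell by 6.72 ± 0.162, Dynap by 6.32 ± 0.425 and Krt8 by 4.84 ± 0.338. Trp53i11 rose by 5.95 ± 0.797, the peptide hormone gene Apela by 4.93 ± 0.537 and the secreted olfactomedin Olfml3 by 4.87 ± 0.728. The largest adjusted p of these genes was 3.57e-05. Of the smooth muscle and epithelial list 8 of 18 fell (9 adjusted over the list alone, adjusted p 7.53e-08, and 0.0162 with an estimated correlation). SWI/SNF subunits rose in 7 of 20 cases (7 adjusted over the list alone, adjusted p 0.00223, and adjusted p = 0.346 with an estimated correlation), where Smarca2 rose by 1.65 ± 0.321. BMP and TGF-beta response genes fell in 4 and rose in 1 of 16 cases (8 and 2 adjusted over the list alone, adjusted p 0.0391, and adjusted p = 0.298 with an estimated correlation), and Id1 fell by 2.24 ± 0.326. The last of these calls was lost without HRAS then MYC replicate 2 (adjusted p 0.256), HRAS+MYC replicate 2 (adjusted p 0.0914) or 7 (adjusted p 0.0510), or MYC replicates 4 and 5 together (adjusted p 0.0677), and with dim genes left out (adjusted p 0.0648). In all, 2405 genes passed, 1374 higher and 1031 lower, with 1065 without HRAS then MYC replicate 1 and 605 without its replicate 2.

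Set against each other, MYC then HRAS cells were higher than HRAS then MYC cells in Il5ra by 7.06 ± 0.202 (log2, SE), Anxa8 by 5.99 ± 0.599, Krt8 by 5.52 ± 0.421 and Krt19 by 5.31 ± 0.469, and lower in Trp53i11 (−5.95 ± 0.994) and Apela (−4.74 ± 0.669), with adjusted p of 0.000434 or lower in 2 arrays each. The smooth muscle and epithelial list had 6 of 18 up (6 adjusted over the list alone, adjusted p 7.91e-08, and 0.0164 with an estimated correlation). The BMP and TGF-beta list had 3 of 16 up (4 adjusted over the list alone, adjusted p 0.00314, and adjusted p = 0.0717 with an estimated correlation) and the SWI/SNF list 0 of 20 (2 down adjusted over the list alone, adjusted p 0.00164, called lower, and adjusted p = 0.299 with an estimated correlation). In all, 653 genes passed, 338 higher and 315 lower, with 206 without MYC then HRAS replicate 2, 377 without HRAS then MYC replicate 1 and 195 without its replicate 2.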

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

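In this part the tests on MYC replicates 4 and 5 were chosen after the result was seen, and the counts over other splits of the arrays were planned.

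Single arrays lay far from the rest of their group (gap to the nearest array large against the range of the group) in 26 of 217 pairs of a named gene or position with a group, where chance gives about 1 in 20. HRAS replicate 3 had 8 of them, all as the highest HRAS array, with genes of neurons and glia among them. They were Map2 at 9.99 (others 5.20 to 6.18), Bcan 8.73 (5.37 to 5.86), Tubb3 8.08 (5.72 to 6.31), Gpm6a 7.42 (4.04 to 4.56), Slc35f1 6.41 (4.46 to 4.85), Syp 6.45 (5.38 to 5.65), Sncaip 5.63 (4.25 to 4.59) and the proliferation marker Mki67 9.93 (8.82 to 9.13). In the other HRAS arrays Anxa1 was lowest in replicate 5 at 11.53 (others 11.97 to 12.06) and Krt19 highest in replicate 2 at 6.30 (5.36 to 5.58).

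HRAS+MYC replicate 2 was lowest in Tgfb1 at 8.46 (others 9.90 to 10.38), Tgfbi at 7.20 (8.72 to 9.85) and Elavl4 at 3.64 (4.54 to 4.96), and highest in Dkk2 at 5.78 (4.78 to 5.11) and Tspan6 at 5.48 (4.28 to 4.77). Gfap was highest in HRAS+MYC replicate 3 at 6.71 (others 5.03 to 5.57), Slc1a3 lowest in replicate 4 at 4.99 (5.52 to 5.84) and Sox2 lowest in replicate 1 at 9.69 (10.33 to 10.71). Slc1a2 was highest in MYC+Ezh2 replicate 2 at 6.70 (others 6.24 to 6.32). MYC replicate 6 was highest in Gfap at 9.08 (others 4.71 to 5.83) and Gad2 at 7.76 (4.52 to 5.56) and lowest in Tenm3 at 8.65 (9.23 to 9.36). MYC replicate 4 was highest in Crabp1 at 10.29 (others 6.25 to 7.63) and lowest in Vim at 9.16 (11.52 to 12.38), Lgals1 at 8.28 (9.42 to 9.88) and Ror2 at 6.14 (6.81 to 7.16).

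Differences of arrays labelled with added Bmi1 from their parents were unlike in MYC and HRAS cells, by a test, for 485 genes. MYC+Bmi1 arrays did not show Bmi1 raised past the threshold, so these are differences between labelled groups. Among named genes the difference was −5.49 for Calb1, −5.21 for Adgrb3, 4.56 for Gad2 and 5.08 for Pi15, hardly able to fall in MYC. It also differed for the lists MYC and ribosome biogenesis (adjusted p 7.17e-07), mesenchymal and extracellular matrix (adjusted p 6.50e-06), astrocyte (adjusted p 1.57e-05), neural stem and radial glia (adjusted p 0.000887) and SWI/SNF subunits (adjusted p 0.00561). None of these list differences held with an estimated correlation (adjusted p 0.0664 to 0.413). The gene count was 98 and 126 without either HRAS+Bmi1 array, 202 without MYC+Bmi1 replicate 3, 1099 without HRAS replicate 3 and 736 without MYC replicate 6.

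MYC replicates 4 and 5 differed from the other 4 MYC arrays, with 249 genes at least 2-fold below and 336 at least 2-fold above every one of those 4 arrays in both. Neurod1, Nhlh1, Stmn2 and Snap25 were high and the glial and stem cell genes Sox2, Fabp7, Olig2 and Pdgfra low, and 9 of the 26 neuronal members lay above the other arrays and 1 below, with 0 members shared with another list and 17 above the array median in each of the other 4 MYC arrays. Admixed non-dividing neurons, which the gate on the transgene would remove, are argued against, because Sox2 at 1.68% and 5.75% of the lowest other array would need most cells to be neurons, while the cell cycle list had median deviations of 0.0888 and 0.205 from the MYC median in these arrays and did not fall. Mislabelled arrays of a group given HRAS are argued against by first component scores at least 64.6 above all 18 such arrays. Those of MYC+Ezh2 are too, by Ezh2 at least 1 log2 unit below every such array (nearest gap −1.14). At most 10.5% of genes 2-fold off lay on chromosomes 14 and 15, against 7.3% of all genes. Chromosome shifts were under 2-fold, so this cannot exclude them. Also open are a sample of MYC+Bmi1 or from outside the series, and a different tumour or cell state, which may be neuronal. The design gives no group for such a state, so no biological explanation was tested. The MYC+Bmi1 mean lay 1.20 times as far as its own farthest array while the own label gave 1.20 and 1.12.

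Whether chance can explain the counts of changed genes was examined by splitting the same arrays in other ways. Only the real split of 100 reached its count for HRAS against MYC (6655, highest other 5052). The same held for HRAS+MYC against MYC (6818, 3125) and HRAS (4921, 1767). Chance is unlikely there if arrays are independent, which is unknown. For MYC+Ezh2 against MYC 9 of 100 splits gave at least the real 49 genes (highest other 907), for MYC+Bmi1 against MYC 16 of 84 gave at least 30 (highest other 1360), and for MYC+Ezh2 against MYC+Bmi1 22 of 56 gave at least 1 (highest other 84), so chance is not excluded for these counts. Splits that call several times the real count point to a structure of the samples, and the highest one for MYC+Bmi1 grouped MYC replicates 4 and 5 with MYC+Bmi1 replicate 2.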

How the results depend on the processing

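In this part only the setting without MYC replicates 4 and 5 was chosen after the data were seen. The 3 comparisons among HRAS, MYC and HRAS+MYC cells kept their counts within 1.5 times under array weights, quantile normalization, the replicate block, the dim filter, a fit of only the groups compared, tumour types in place of groups and without any 1 array, and only the 2-fold threshold lowered them further, to 2535, 2469 and 1442, by its construction. Counts for added Ezh2 and Bmi1 and for the secondary tumours were less stable, and unless the construction shows it the cause was not tested.

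With the 2-fold threshold the other counts were 24 for MYC+Ezh2 and 16 for MYC+Bmi1 against MYC, 680 for HRAS+Bmi1 against HRAS, 2055 for MYC then HRAS against MYC, 1106 for HRAS then MYC against HRAS and 1098 against HRAS+MYC. Array weights, which gave the arrays unequal influence, raised counts to 554 for MYC+Ezh2 and 61 for MYC+Bmi1 against MYC, 2 between these 2 groups, 3460 for HRAS+Bmi1, 4384 for HRAS then MYC against HRAS, 150 for MYC then HRAS and 5085 for HRAS then MYC against HRAS+MYC, 1870 between these 2 groups and 1711 for the Bmi1 difference. In a fit of only the groups compared, with fewer arrays to estimate the spread, counts were 1 for MYC+Ezh2 and 1 for MYC+Bmi1 against MYC, 533 for HRAS+Bmi1, 2367 for MYC then HRAS against MYC, 983 for HRAS then MYC against HRAS, 3 for MYC+Ezh2 against MYC+Bmi1 and 135 for the Bmi1 difference. Without MYC replicates 4 and 5 counts were 202 for MYC+Ezh2, 245 for MYC+Bmi1 and 745 for the Bmi1 difference. The position of MYC then HRAS arrays above MYC arrays was 0.875 (exact p = 0.0667, the smallest possible). The Sox2 difference between HRAS+MYC and MYC cells turned from 1.02 to −0.80. 

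The replicate numbers do not pair the arrays: 79 pairs of the same number in different groups had a median correlation of deviations of 0.0122, against −0.00229 in 355 pairs of different numbers, 11 of the 79 exceeded 0.1, and 9 of 32 arrays correlated best with an array of their own number. With a replicate block the MYC+Ezh2 count was 9, other counts stayed within 1.5 times, and 16 named genes and 5 lists lost and 2 genes and 7 lists gained their call.

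With any 1 array left out, counts ranged from 5985 to 6820 (HRAS against MYC), 6282 to 6728 (HRAS+MYC against MYC), 4152 to 4779 (HRAS+MYC against HRAS), 4 to 233 (MYC+Ezh2), 9 to 234 (MYC+Bmi1), 1 to 11 (MYC+Ezh2 against MYC+Bmi1), 199 to 1801 (HRAS+Bmi1), 1900 to 4286 (MYC then HRAS against MYC), 544 to 2667 (HRAS then MYC against HRAS), 15 to 43 and 605 to 2444 (these groups against HRAS+MYC), 195 to 578 (against each other) and 98 to 1099 (the Bmi1 difference). Where 1 array of a group of 2 was left, it is assumed to vary like the other groups. Positions ranged from 0.809 to 0.916 above MYC and 0.280 to 0.372 above HRAS arrays, and from −0.113 to −0.00561 and −0.541 to −0.484 against HRAS+MYC arrays. The exact p was 0.0667 for HRAS then MYC above HRAS without any 1 HRAS array, the smallest that the arrays left can give. With 1 secondary array left, no exact p below 0.05 can be reached. MYC then HRAS did not pass against HRAS+MYC in any setting. With 1 array left out 66 to 80 lists were called, against 73.

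Of 312 list results 215 kept their side of the threshold in every alternative and 56 calls were lost in at least 1, all 56 with an estimated correlation, which left 17 called lists. Leaving out dim genes ended 15 list calls and added 3, and quantile normalization ended 2 and added 4. Of 300 named gene results 206 kept theirs in every alternative and 77 lost it in at least 1, 52 in a fit of only the groups compared, 3 with quantile normalization, and 1 each with array weights, the mean of probe sets and the trended prior. Without background values, dim genes cannot be told from absent ones.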

Other observations

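In this part the tests on Myc levels and on chromosomes and the genes named here were chosen after the values were seen.

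Growth regulators moved gene by gene in lists that were not called as a whole. In HRAS against MYC cells, with 5 of 5 HRAS arrays beyond every one of 6 MYC arrays for each gene named, the cell cycle inhibitors Cdkn2b (3.66 ± 0.296, log2, SE, adjusted p 1.60e-10) and Cdkn2a (1.84 ± 0.154, adjusted p 2.81e-10), the ligand Bmp2 (3.48 ± 0.404, adjusted p 1.13e-07) and the chromatin protein Hmga2 of the embryonal list (4.57 ± 0.161, adjusted p 5.05e-18; 2 rose and 2 fell of 16) were higher. Of the growth regulators silenced by Polycomb 7 rose and 5 fell of 18 (8 and 5 adjusted over the list alone, list adjusted p 0.115), with Igfbp3 (4.00 ± 0.517, adjusted p 6.10e-07) also up. Of the p53 targets 6 rose and 3 fell of 17 (6 and 4 adjusted over the list alone, list adjusted p 0.464), with Plk2 (2.53 ± 0.412, adjusted p 1.86e-05) up and Sesn1 (−1.71 ± 0.213, adjusted p 3.64e-07) and Btg2 (−1.89 ± 0.314, adjusted p 2.52e-05) down, in cells whose p53-deficient background was shared by the groups. Of the WNT genes 1 rose and 5 fell of 13 (2 and 5 adjusted over the list alone, list adjusted p 0.464), where Wnt7b rose by 4.58 ± 0.293 (adjusted p 1.75e-12) and the receptor Lgr5 fell by 3.17 ± 0.308 (adjusted p 4.89e-09). With any 1 array left out the highest adjusted p of these genes was 0.000181.

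Cells with both oncogenes differed from HRAS cells in genes of the same lists. In HRAS+MYC against HRAS cells, with 7 of 7 arrays beyond every one of 5 HRAS arrays, Igfbp3 fell by 3.86 ± 0.50 (log2, SE, adjusted p 1.73e-06), Cdkn2c by 2.10 ± 0.347 (adjusted p 4.77e-05) and Wnt7b by 1.62 ± 0.283 (adjusted p 9.79e-05), while the desmosome protein Perp rose by 3.99 ± 0.427 (adjusted p 1.01e-07) and the WNT antagonist Notum by 2.23 ± 0.221 (adjusted p 2.73e-08). Rnf43, which also restrains WNT signalling, rose by 1.73 ± 0.253 (adjusted p 9.36e-06) in 6 of 7 arrays. With any 1 array left out the highest adjusted p was 0.000670. The p53 target (5 up and 4 down of 17, 5 and 5 adjusted over the list alone, adjusted p 0.706), Polycomb-silenced (1 and 6 of 18, 1 and 6, adjusted p 0.0701) and WNT lists (3 and 1 of 13, 3 and 1, adjusted p 0.565) were not called.

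Myc was higher in HRAS cells than in cells given MYC. In HRAS replicates 1 and 2 the neighbours Lratd2 (10.67 and 12.55, highest other array 9.52) and Pvt1 (10.62 and 11.84, highest other array 8.99) lay at least 1.15 above every other array, so a gain of this neighbourhood is a candidate explanation there, though not one that reaches Trib1 beyond Lratd2 (8.39 and 9.03, highest other array 9.86), while in HRAS replicates 3 to 5 and HRAS+Bmi1 Lratd2 reached at most −0.323 from the highest MYC array, which argues against a gain across both genes, and Pvt1 reached 0.891 above it, so a shorter gain stays open. The difference of 4.35 between HRAS and MYC cells and the gap of 2.13 between all 7 arrays without MYC and all 25 with it are the pattern itself, so whether the probe set reads the transgene, and whether the endogenous gene is repressed where MYC was added, stays open.

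Chromosomes were shifted as a whole or in part in some arrays. Of 640 pairs of array and chromosome 26 lay beyond 100 reshuffled tables (largest shift there 0.208), and 14 pairs in 8 arrays reached 0.3, among them chromosome 14 (−0.611) and 15 (0.407) in MYC replicate 4, chromosomes 14 (−0.397), 15 (0.414) and 19 (−0.385) in MYC replicate 5, chromosome 18 in HRAS replicate 3 (0.486) and chromosome 16 in both HRAS+Bmi1 arrays (−0.487 and −0.477). Normalization is argued against, since the smallest of these shifts exceeded the largest array median by 0.213, and so are a few strong genes, since at least 67.0% of a chromosome's genes lay on the shifted side. Gain or loss of whole chromosomes may explain 12 pairs, where the first and second part of the gene order were shifted by at least 0.251, but not chromosome 4 in HRAS+Bmi1, where the first part of the gene order was shifted by at most 0.096 and the second by −0.488 and −0.531, so a partial loss stays open there. DNA was not analysed here, and the design gives no group for these shifts.

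In MYC+Bmi1 replicates 1 and 3 Commd3, the neighbour of Bmi1 in the genome, was 6.51 and 5.53, while it was 9.51 in replicate 2 and 8.56 to 9.70 in all arrays of other groups. Neurod1 was 7.87 in MYC+Bmi1 replicate 1 against 3.49 and 3.37 in replicates 2 and 3. Eif2s3y minus Uty was lower in HRAS+MYC than in HRAS arrays by an exact test chosen after its values were seen (−2.30, p = 0.0101), but Eif2s3y was at 3.77 in HRAS+MYC replicate 2, near the floor. The 2 HRAS+Bmi1 arrays were closer to each other than any other pair within a group (SD of the difference 0.255 against 0.30 to 0.799) but shared only 13 identical values, so they are separate measurements, and a single culture of origin was not tested.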
